A study of Mus musculus with 12 samples.

How the data were processed

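RNA from LT-HSCs of mouse bone marrow was extracted with TRIzol and made into poly-A libraries with the TruSeq version 2 chemistry, per the labels' protocols. The deposited table holds raw read counts per gene for 12 libraries, whole numbers that were not normalised. Per the submitters' processing notes, the authors used STAR 2.3.0e, featureCounts and Subread with the mm10 build (versions of the last 2 tools, the annotation and the strand setting are not given in the sources used here). Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart, and reads of near-identical paralogs may be split between them or lost.

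Each column was matched to its sample through the sample description. Groups came from the titles (6 wt and 6 libraries labelled Jak1 KO), and the name set (VD or ZL, 3 libraries of each genotype in each) came from the descriptions. Whether the name sets were separate collections is not stated. Gene positions and exon lengths were taken from RefSeq of GRCm38.p6 and GENCODE annotation of the same assembly (mm10): 23276 of the 23472 symbols matched, 1629 of them as older symbols, and 13072 of the 13184 tested genes had an exon length.

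Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on genotype, library sizes were scaled by TMM, and the model held a term for name set and a term for genotype. Genotype was tested with the quasi-likelihood F test (glmQLFit, glmQLFTest) and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Fold changes are the libraries labelled Jak1 KO over wt on the log2 scale, and their SE was the fold change divided by the square root of F. Normalised CPM uses the TMM-scaled library sizes. Values after ± are SDs. Log2 CPM, used for list scores, principal components and permutation tests, had a prior count of 2. The difference of the genotype effect between name sets was tested as an interaction term, and each set was also fitted alone. Jak1 was tested by exact permutation of genotypes within name sets.

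The 29 gene lists and cell type marker lists were written before the data were examined, as were the design, the naming rule and 17 of the alternatives. The 28 lists with at least 3 tested members were compared with all other genes by camera with a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated and with fry (limma 3.58.1). The mitochondrially encoded list had 0 of its 15 genes in the table and was not tested. Genes were named by rule: Jak1 first, then up to 12 genes per direction with the largest fold change among those past the threshold, with a mean of at least 1 CPM and the same sign in both sets. Up to 4 members of each list with the smallest p followed, or 2 where none passed, together with Jak2, Tyk2, Stat3, Stat5a, Stat5b and others fixed beforehand. Some genes that the rule takes are not reported here. Uncharacterised gene models were passed over. Other genes named were chosen after their values were seen: Isg15, Ifitm1, H2-K1, B2m, Ciita, the H2-DM and H2-O genes, Tap1, H2-Q5, Apol9b, Irgm1, Irgm2, Pf4, Vwf, Selp, Plek, Ly6a, Beta-s and the genes named only in the closing part.

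On simulated counts with the real means and library sizes, 100 genes changed by 1 and 100 by 2 on the log2 scale among 13184. For the 6 against 6 comparison edgeR recovered 50% of the former and 90% of the latter with 3.29% false calls, DESeq2 64% and 94% with 14.7% false calls, and limma-voom 51% and 88% with 2.67%. The interaction test recovered 0% and 32%, with 15.8% false calls. Camera called the 1 list shifted by -0.7 and 0 of 20 unshifted lists, in simulated counts whose genes varied independently.

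Depth ranged from 8989965 to 28701855 counts per library. Where a group had 0 counts, the floor was 3 counts over the group. Intervals are at 95%, and floors cover counting error only, since reads were counted without molecular identifiers. The 45S ribosomal RNA gene Rn45s took 14.8% to 22.6% of the counts in VD libraries and 0.511% to 0.950% in ZL libraries, and stayed in the library sizes.

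The alternatives were DESeq2's size factors, upper quartile factors, no filter on low counts, a filter of 1 CPM in 6 libraries, the DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, robust dispersion, no set term, replicate number as a block, each set alone, each library left out in turn, a term for sex inferred from Xist and Y-linked genes, an adjusted p of 0.1, and a log2 fold change of at least 1 in addition. Added after the data were seen were an offset for each library's trend on exon length, 1 surrogate variable (sva 3.50.0), Rn45s and Lars2 left out, and the 3 ZL libraries farthest along the first principal component (Jak1 KO 4, Jak1 KO 6 and wt 6) left out together.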

Results

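Poly-A RNA was sequenced from long-term haematopoietic stem cells (LT-HSCs), the rare bone marrow cells that sustain blood production, of C57BL/6 mice. The labels gave 6 wt libraries, from cre-negative animals, and 6 libraries labelled Jak1 KO, from cre-positive animals. Poly(I:C), a double-stranded RNA that induces interferon and switches on interferon-driven cre, had been given to both groups in 4 doses, 4 to 6 weeks before harvest. In each genotype 3 libraries carried names of a VD series (replicates 1 to 3) and 3 carried names of a ZL series (replicates 4 to 6). Total counts were 16798427, 9824802, 11790642, 22668542, 28261886 and 25544261 in wt libraries 1 to 6. They were 13694678, 8989965, 10332245, 13804931, 28701855 and 22735452 in the libraries labelled Jak1 KO 1 to 6. The table held 23472 genes, of which 13184 passed the filter on low counts. Nothing in the labels said that the libraries of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical in part. Xist and Y-linked genes placed both sexes in each genotype of each name set, so each such group of 3 held at least 2 animals. No 2 libraries of a group within a name set agreed within sampling noise, the lowest chi-square per degree of freedom being 14.1.

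Jak1, the tyrosine kinase that signals for interferon and many interleukin receptors, was counted at 374 ± 45.3 normalised CPM in wt libraries and at 422 ± 161 in libraries labelled Jak1 KO (SD, n = 6 each). The gene lies on chromosome 4 from 101151974 to 101265282 (GRCm38). Its log2 fold change was 0.18 (SE 0.20, edgeR adjusted p = 0.945), with a 95% interval of -0.26 to 0.62. Within the name sets the log2 fold change was 0.24 in VD and 0.15 in ZL, and an exact two-sided permutation test within sets gave p = 0.635 over 400 relabelings (smallest possible 0.005). The library labelled Jak1 KO 6 held the highest value, 727 CPM, and without it the log2 fold change was -0.046. The gene-level count includes exons that a conditional deletion leaves in place, and the labels do not say which exons were removed, so this count does not check the labels. For that reason the group is called "labelled Jak1 KO" throughout. The other kinases of the family did not pass the test, with log2 fold changes of -0.51 for Jak2 (SE 0.31) and -0.31 for Tyk2 (SE 0.31). Stat3, Stat5a and Stat5b did not pass either, at -0.30, -0.28 and -0.20.

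The comparison between genotypes asked which transcripts differ between LT-HSCs labelled Jak1 KO and wt. Since only the former animals were cre-positive, effects of cre cannot be told apart from those of a Jak1 deletion. Interferon-response genes and MHC class II genes were lower in the libraries labelled Jak1 KO. Irf9, a transcription factor of the interferon response, fell from 123 ± 36.6 to 47.1 ± 7.43 CPM, which was 2.55-fold lower (log2 fold change -1.35, SE 0.14, edgeR adjusted p = 0.00034). Iigp1, an interferon-inducible GTPase, was 6.17-fold lower. All 6 libraries labelled Jak1 KO lay below every wt library of their name set for both genes. Only 1 gene was higher, Rgs7bp, a membrane anchor of regulators of G-protein signalling, at 26.1 ± 8.45 against 10.2 ± 3.76 CPM.

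In all, 58 of the 13184 genes passed edgeR's adjusted p of 0.05, 57 lower and 1 higher in the libraries labelled Jak1 KO, and 667 had an unadjusted p under 0.05. The 57 lower genes had a median log2 fold change of -1.92 and ranged from -0.67 to -6.34. For 56 of them every library labelled Jak1 KO lay below every wt library in both name sets. Chance gives this arrangement to 0.25% of genes not chosen for a difference, but these were chosen on the same libraries, so their count tests nothing. Of the 57, 34 belonged to the lists of interferon or MHC genes and 23 did not. Those lists do not hold every such gene: H2-Q5, a class I gene, is among the 23, which are therefore not all unrelated to interferon or MHC. Each of the 12 fits that left out 1 library kept 37 of the 58 genes, and the count ranged from 39 to 77. Rgs7bp passed only in the fits without wt 5 or without Jak1 KO 6, and its adjusted p reached 0.144 in the others.

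**Figure D1:**
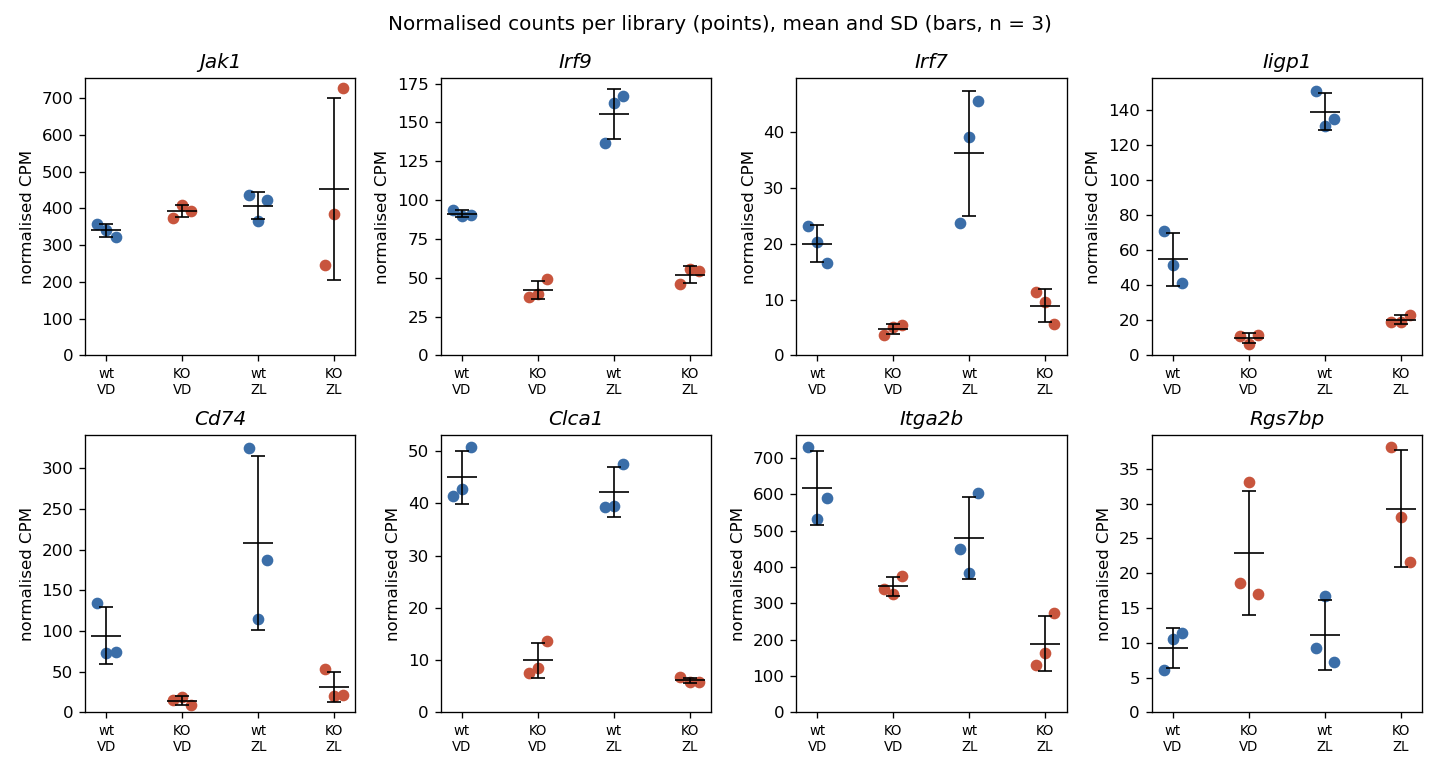
Normalised CPM (y axis, starting at 0) of Jak1 and 7 genes past the threshold in each library, by genotype and name set (x axis); points are libraries, bars the mean and SD of 3. The libraries labelled Jak1 KO lay below the wt libraries of their set for Irf9, Irf7, Iigp1, Cd74, Clca1 and Itga2b and above them for Rgs7bp, and not for Jak1.

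Antiviral effectors of the type I interferon response were among the genes with the largest differences that the naming rule took, next to Serping1. Apol9b, an apolipoprotein L gene outside that rule, was also far lower (1.95 ± 0.745 and 0.0332 ± 0.0530 CPM). Oas2, which makes the 2-5A messenger that activates RNase L, was at 29.2 ± 3.15 CPM in the VD wt libraries (n = 3) and had 0 counts among 33016888 in the 3 VD libraries labelled Jak1 KO. With a floor of 3 counts over that group this was at least 305-fold lower, so that at most 0.327% of the wt level remained, a bound on counting error only. In ZL the libraries labelled Jak1 KO did hold Oas2 counts (1, 25 and 14), at 0.476 ± 0.366 CPM against 21.1 ± 21.0 in wt (log2 fold change -5.33, SE 0.94, adjusted p = 0.395 in ZL alone). Over all 12 libraries Oas2 was 81.0-fold lower (log2 fold change -6.34, SE 0.74). Oasl1 was 12.2-fold lower (log2 fold change -3.61, SE 0.46, edgeR adjusted p = 0.00111) and Phf11d 9.39-fold lower (-3.23, SE 0.40). Rtp4, a receptor transporter protein with antiviral activity, was 7.99-fold lower (SE 0.36 on the log2 scale). Irf7, the master regulator of type I interferon genes, was 4.17-fold lower (-2.06, SE 0.23), and Ifi44 was 4.02-fold lower. Mx1, Oas3 and Cxcl10 also fell, with log2 fold changes of -3.80, -2.63 and -3.45, and Cxcl10 had 0 counts in the same 3 libraries as Oas2. Each of these 3 genes lost its call in some of the fits that left out 1 library. Mx1 passed only without wt 4 among the 12 fits that left out 1 library (adjusted p up to 0.140). Oas3 missed the threshold without any of wt 1, wt 2, wt 3, Jak1 KO 1, Jak1 KO 2, Jak1 KO 3 or Jak1 KO 5 (up to 0.104). Cxcl10 missed it without wt 5 or any library labelled Jak1 KO other than Jak1 KO 4 (up to 0.120).

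As a list, the type I interferon genes had 57 tested members, of which 21 were lower, 0 higher and 36 not past the threshold. Adjusted over the list alone, 42 were lower and 1, Ifitm1, higher. Their median log2 fold change was -0.75, with 56 of the 57 fold changes below 0 (camera adjusted p = 5.01e-93, and adjusted p = 0.000406 with an estimated correlation). Isg15, a ubiquitin-like modifier, stood at 10.3 CPM in wt and 4.12 in the libraries labelled Jak1 KO and did not pass (adjusted p = 0.123), except without Jak1 KO 4 (0.0322). Ifitm1, an interferon-induced membrane protein gene, lay at 296 CPM in wt and 476 in the libraries labelled Jak1 KO (log2 fold change 0.62, adjusted p = 0.902 over all genes).

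The list of interferon gamma response and MHC class I genes had 37 tested members, 9 lower, 0 higher and 28 not past the threshold, with 19 lower when adjusted over the list alone. The median log2 fold change was -0.52 (camera adjusted p = 1.93e-51, and adjusted p = 5.01e-05 with an estimated correlation). Iigp1 had the smallest p of the list (log2 fold change -2.63, SE 0.19, edgeR adjusted p = 2.43e-05), and Igtp was 2.62-fold lower. Of the related GTPase genes in the list, Irgm2 was 3.02-fold lower, and Irgm1 was not past the threshold (-0.62, adjusted p = 0.0602) except without Jak1 KO 4 (0.0247). Tgtp1 and Tgtp2 were 4.64-fold and 3.09-fold lower, but these near-identical paralogs share reads, so their separate values are uncertain. Tap1, a peptide transporter of the class I pathway, fell from 258 ± 22.3 to 126 ± 20.5 CPM (2.06-fold, adjusted p = 0.00169). H2-Q5, a class I gene outside the list whose paralogs may share its reads, was 2.39-fold lower. The abundant H2-K1, lower when adjusted over the list alone, and B2m were not past the threshold over all genes. H2-K1 stood at 2368 CPM in wt and 1753 in the libraries labelled Jak1 KO (adjusted p = 0.825) and B2m at 2745 and 2123 (adjusted p = 0.872). The library labelled Jak1 KO 4 decided this. It held 3916 and 5212 CPM, above every wt library, while the other 5 lay below every wt library of their name set. That library also had the lowest limma-voom quality weight (0.165) and lay farthest along the first principal component (-84.8). Relative to its name set, its log2 CPM fell with exon length (Spearman -0.52). Whether these traits account for its values was not tested. Without Jak1 KO 4 both genes were lower, with log2 fold changes of -0.77 (SE 0.10, adjusted p = 0.00152) and -0.75 (SE 0.13, adjusted p = 0.0217). Since that library was singled out for its high values of these genes, this result was nearly fixed and tests nothing. Calls gained without Jak1 KO 4, here and for other genes, carry no allowance for the choice of that library.

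MHC class II genes, which present antigen to helper T cells, had 10 tested members, of which 4 were lower and 0 higher, and 5 were lower when adjusted over the list alone. Cd74, the invariant chain, was 6.55-fold lower, at 151 ± 94.9 CPM in wt and 23.1 ± 15.4 in the libraries labelled Jak1 KO (log2 fold change -2.71, SE 0.33, edgeR adjusted p = 0.000824). H2-Aa was 5.70-fold lower, H2-Eb1 8.68-fold lower and H2-Ab1 3.79-fold lower. H2-Eb1 missed the threshold without Jak1 KO 2 (adjusted p = 0.0550), and H2-Ab1 without Jak1 KO 1, Jak1 KO 2 or Jak1 KO 3 (up to 0.0566). Their transactivator Ciita, the fifth gene of the list-alone count, had a log2 fold change of -1.10 (adjusted p = 0.203 over all genes). Of the peptide-loading genes, H2-DMa stood at 138 and 133 CPM and H2-Ob at 23.4 and 23.3. The list's median log2 fold change was -0.64 (camera adjusted p = 1.31e-16, and adjusted p = 0.0240 with an estimated correlation). The library labelled Jak1 KO 4 was an exception, with a mean log2 CPM over the list of 5.04, between wt 6 (4.97) and wt 5 (5.11), while the other 5 ranged from 2.90 to 3.74. B-cell markers did not move the same way, with 6 of 6 tested members above 0 and 0 past edgeR's threshold (0 at an unadjusted p under 0.05 and 0 with DESeq2; median 0.25, camera adjusted p = 0.196). Without wt 3 camera's adjusted p for B-cell markers was 0.0391, toward higher.

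**Figure D2:**
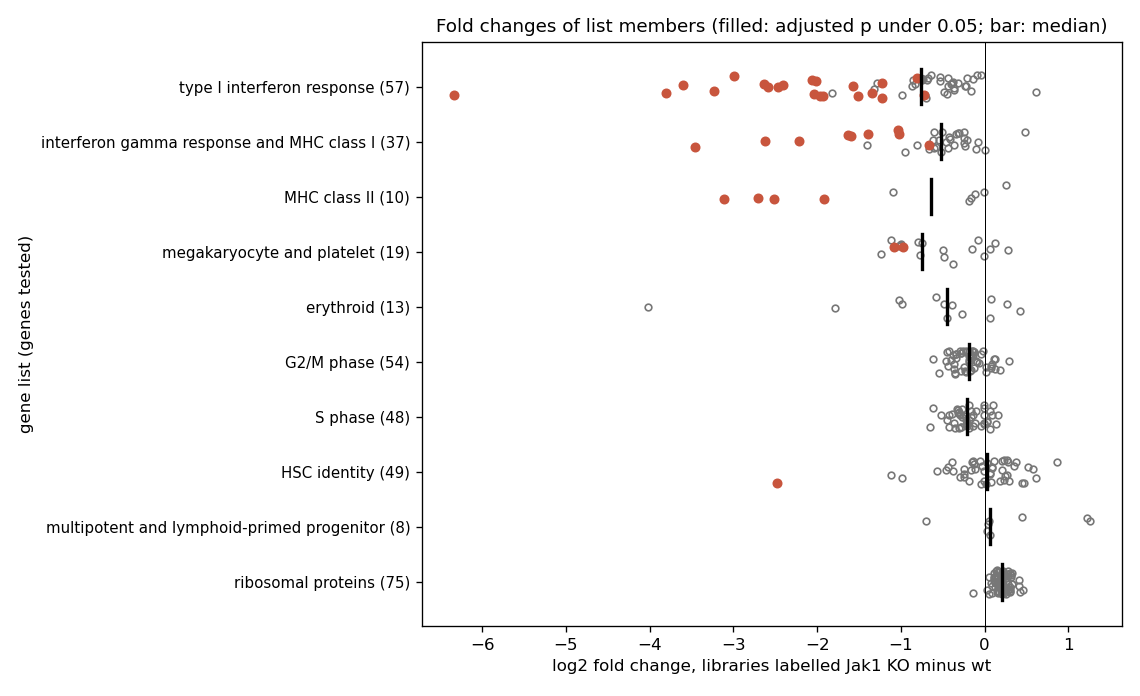
Log2 fold changes (x axis) of the tested members of 10 gene lists (y axis, number of genes tested in parentheses), filled where edgeR's adjusted p was under 0.05, with a bar at the median. The interferon and MHC class II lists and the megakaryocyte list extend to the left, and the medians of the G2/M, S-phase and ribosomal lists lie nearer 0, at -0.18, -0.21 and 0.21.

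Megakaryocyte and platelet genes were also lower in the libraries labelled Jak1 KO. Itga2b, the platelet integrin subunit CD41, fell from 548 ± 123 to 268 ± 99.8 CPM (log2 fold change -1.08, SE 0.20, edgeR adjusted p = 0.0247), and F2r, the thrombin receptor, from 332 ± 160 to 163 ± 79.0 CPM (-0.98, SE 0.20, adjusted p = 0.0473). Of 19 tested members these 2 were lower, 0 higher and 17 not past the threshold, and 6 were lower when adjusted over the list alone. The median log2 fold change was -0.74, with 16 of 19 below 0 (camera adjusted p = 1.72e-10, and adjusted p = 0.000446 with an estimated correlation). Not past the threshold on their own were Pf4 (-1.24, SE 0.37), Vwf (267 and 139 CPM), Selp (-1.02, SE 0.29) and Plek (-1.01, adjusted p = 0.0640). Pf4 stood at 419 CPM in the library labelled Jak1 KO 4 and at 47.4 to 129.7 CPM in the other 5, each of which lay below every wt library of its name set. Without Jak1 KO 4 both Pf4 (log2 fold change -1.73, SE 0.24, adjusted p = 0.00272) and Plek (-0.84, adjusted p = 0.0329) passed, and Vwf and Selp did not. Itga2b missed the threshold without wt 1, wt 4, Jak1 KO 1, Jak1 KO 2 or Jak1 KO 5 (adjusted p up to 0.0987), and F2r passed only in the fits without Jak1 KO 4 or without Jak1 KO 6 (up to 0.162 in the others). Gata1, a transcription factor of the erythroid, megakaryocyte and mast cell lineages, lay at 77.7 ± 18.9 CPM in wt and 43.6 ± 16.8 in the libraries labelled Jak1 KO, just outside the threshold (adjusted p = 0.0539, and 0.00767 without Jak1 KO 4).

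Among stem cell identity genes, 1 of 49 tested members passed. This was Clca1, the older symbol of Clca3a1, a member of the calcium-activated chloride channel regulator family, which was 5.57-fold lower (43.5 ± 4.65 against 8.04 ± 2.95 CPM, log2 fold change -2.48, SE 0.20, edgeR adjusted p = 3.54e-05). The table also holds close relatives of this gene, which may share its reads. The list did not shift as a whole in 1 direction (median 0.02, camera adjusted p = 0.903). Of its 49 genes, however, 11 had an unadjusted p under 0.05, against 667 of all 13184, and DESeq2 called 1. For changes in either direction, Clca1 included, fry gave an unadjusted p of 0.000265. Ly6a, which encodes the stem cell antigen Sca-1, stood at 85.7 and 48.0 CPM (log2 fold change -1.12, adjusted p = 0.457). It was at 159.9 CPM in the library labelled Jak1 KO 4 and at 12.2 to 44.6 CPM in the other 5, each below every wt library of its name set. Without Jak1 KO 4 it was lower, 3.02-fold (log2 fold change -1.60, SE 0.15, adjusted p = 0.000196). Lower genes outside the interferon, MHC and marker lists that the naming rule took included Serping1, the C1 esterase inhibitor (10.3-fold lower), Kcnj5, a potassium channel subunit (6.29-fold lower), and Slco2a1, a prostaglandin transporter (7.35-fold lower). Slco2a1 missed the threshold without wt 1, wt 2, wt 3, wt 4, Jak1 KO 1, Jak1 KO 3 or Jak1 KO 5 (adjusted p up to 0.0903).

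Cell cycle lists lay slightly lower in the libraries labelled Jak1 KO, by amounts that camera with an estimated correlation did not separate from those of the other genes. Tested with fry against no change, G2/M genes passed (adjusted p = 0.0193) and S-phase genes did not (0.134). G2/M genes had a median log2 fold change of -0.18, with 44 of 54 below 0 (camera adjusted p = 1.16e-06, adjusted p = 0.165 with an estimated correlation). S-phase genes had a median of -0.21, with 40 of 48 below 0 (1.10e-05, and adjusted p = 0.357 with an estimated correlation). In both lists 0 members passed with edgeR, where 7 G2/M genes and 6 S-phase genes had an unadjusted p under 0.05 and DESeq2 called 1 and 0. Ckap2l, a spindle protein gene, came nearest, at 120.3 CPM in wt and 78.3 in the libraries labelled Jak1 KO, and was the 1 G2/M gene lower when adjusted over the list alone. Camera with an estimated correlation did not pass either for the JAK-STAT core list, in which 2 of 17 members passed, over all genes and over the list alone, Irf9 among them (median -0.20, camera adjusted p = 3.68e-06, adjusted p = 0.357 with an estimated correlation). Nor did it for the MYC target list (median -0.10, 0.0163 and adjusted p = 0.763 with an estimated correlation), in which edgeR called 0 of 44 genes, DESeq2 0, and 3 had an unadjusted p under 0.05. The MYC target call was lost without wt 2, Jak1 KO 1, Jak1 KO 3 or Jak1 KO 6 (camera adjusted p up to 0.264). Ribosomal protein genes had a median of 0.21, with 74 of 75 above 0 and 0 past the threshold with edgeR, with DESeq2 or at an unadjusted p under 0.05 (2.24e-05, adjusted p = 0.772 with an estimated correlation). Without Jak1 KO 4 the list's direction turned to lower (camera adjusted p = 0.968).

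Lineage markers were compared in the same way. The erythroid list had a median of -0.45 (camera adjusted p = 0.0194, adjusted p = 0.266 with an estimated correlation). Of its 13 genes edgeR called 0 and DESeq2 1, 3 had an unadjusted p under 0.05, and 1 was lower when adjusted over the list alone. That gene was Aqp1, a water channel of red cells, at 95.9 ± 38.3 and 50.2 ± 25.4 CPM (adjusted p = 0.178 over all genes). Haemoglobin beta (Beta-s) reached 3449 CPM in wt 2 against at most 7.03 in the other 11 libraries, and without wt 2 camera's adjusted p for the list was 0.239. The call was also lost without Jak1 KO 1, Jak1 KO 3 or Jak1 KO 6.

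Of the 8 tested multipotent and lymphoid-primed progenitor markers, edgeR called 0 and DESeq2 1, 2 had an unadjusted p under 0.05, and 2 were higher when adjusted over the list alone (median 0.06, mean 0.30, camera adjusted p = 0.0307, adjusted p = 0.243 with an estimated correlation). These were Satb1, a chromatin organiser of lymphoid cells, at 4.33 ± 1.81 and 10.3 ± 4.41 CPM (past the threshold over all genes without Jak1 KO 4, adjusted p = 0.0157), and Flt3, the receptor of multipotent progenitors, at 30.7 ± 3.84 and 41.8 ± 6.64 CPM (adjusted p = 0.674 over all genes). The list's call was lost without wt 3, wt 4, Jak1 KO 1, Jak1 KO 2, Jak1 KO 5 or Jak1 KO 6 (camera adjusted p up to 0.134).

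The remaining lists did not pass, and edgeR called 0 of their members, with 0 to 5 per list at an unadjusted p under 0.05. DESeq2 called 1 gene each in the cytokine receptor, quiescence, p53, immediate early and mast cell lists and 0 in the others. Their medians were -0.19 for feedback and STAT3 or STAT5 targets (camera adjusted p = 0.551), 0.05 for cytokine receptors (0.992), 0.02 for quiescence genes (0.992) and 0.09 for nuclear oxidative phosphorylation genes (0.592). They were -0.01 for glycolysis and hypoxia (0.992), -0.09 for p53 targets (0.903), 0.06 for NF-kB and inflammatory genes (0.992), -0.16 for immediate early genes (0.567) and 0.04 for the BCL2 family (0.660). Among markers of other cell types the medians were 0.16 for myeloid progenitors and neutrophils (0.104), 0.14 for monocytes, macrophages and dendritic cells (0.903) and -0.14 for mast cells and basophils (0.119). They were 0.13 for T and NK cells (0.567), -0.01 for endothelial and stromal cells (0.992) and -0.11 for sex-linked genes (0.992). Adjusted over the list alone, Btg2, an antiproliferative gene, was the 1 gene lower in the quiescence, p53 and immediate early lists (26.0 ± 9.70 and 13.3 ± 3.31 CPM, edgeR adjusted p = 0.0521 over all genes), Gata1 was the 1 gene lower in the mast cell list, and 0 genes passed in the others. The median, the mean and camera's direction did not share a sign for stem cell identity, cytokine receptors, quiescence, glycolysis, p53 targets, NF-kB, the BCL2 family, monocytes, endothelial cells and sex-linked genes. Single libraries decided 3 of these results: mast cell genes were lower without Jak1 KO 4 (camera adjusted p = 0.00280) or wt 2, and nuclear oxidative phosphorylation genes lower without Jak1 KO 4 (0.000113) and higher without Jak1 KO 6. Neutrophil genes were higher without wt 3 (0.000994), wt 5, Jak1 KO 1 or Jak1 KO 5. These fits used the preset correlation, and an estimated one was not run with a library left out. Over all 12 libraries camera with an estimated correlation gave adjusted p = 0.653 for mast cell genes, 0.994 for nuclear oxidative phosphorylation genes and 0.772 for neutrophil genes.

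The second comparison asked whether the difference between genotypes was the same in both name sets. Each of the 57 lower genes had a negative fold change in VD and in ZL, but they were called on both sets together, which nearly fixes that sign. Over all tested genes the log2 fold changes of the sets correlated at 0.249 (Pearson) and 0.105 (Spearman). In the VD set alone 142 genes passed edgeR's threshold, 96 lower and 46 higher, and these included 43 of the 58. In the ZL set alone 0 passed, with 211 at an unadjusted p under 0.05. The interaction of set and genotype reached the threshold for 0 genes with edgeR (182 at an unadjusted p under 0.05) and for 1 gene with DESeq2. The libraries varied more in ZL, with a biological coefficient of variation of 0.413 against 0.190 in VD. Of the 96 genes lower in VD, 86 were also lower in ZL (median -0.93, camera p = 7.14e-86, and p = 0.000189 with an estimated correlation), among them 47 of the 54 outside the interferon and MHC lists. Of the 46 genes higher in VD, 30 were higher in ZL (median 0.15, camera p = 0.0122, and p = 0.482 with an estimated correlation). In VD alone neutrophil and myeloid progenitor markers had a median of 0.19 (camera adjusted p = 0.0119), against an adjusted p of 0.104 in all 12 libraries and adjusted p = 0.772 with an estimated correlation there.

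**Figure D3:**
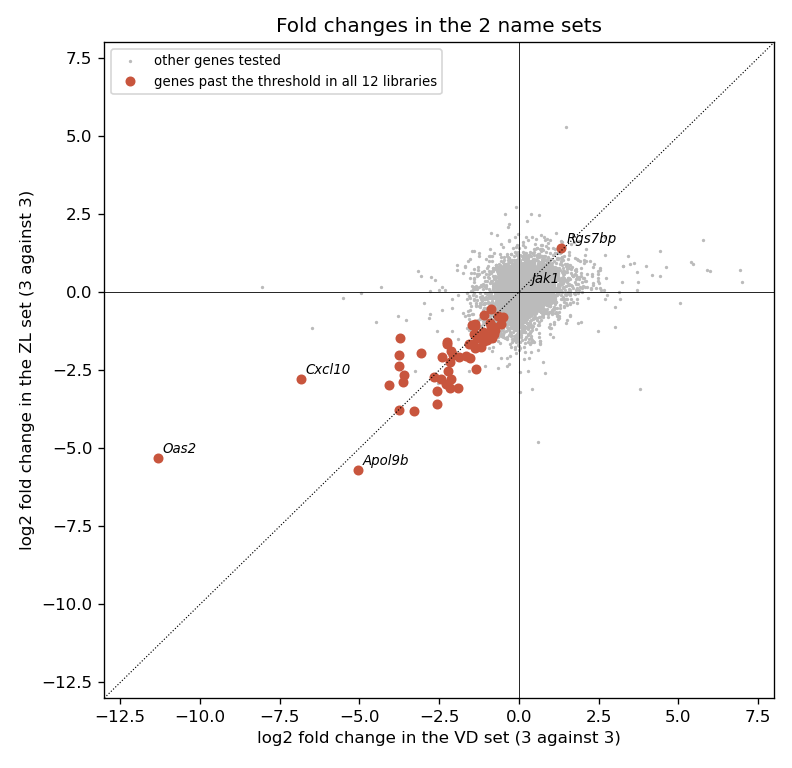
Log2 fold change of each tested gene in the VD set (x axis) against the ZL set (y axis), with the 58 genes past the threshold in all 12 libraries as large points and equality as a dotted line. The 57 lower genes sit in the lower left quadrant and Rgs7bp in the upper right; the fitted VD values of Oas2 and Cxcl10 have 0 counts on one side and are no bounds.

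Gene lists were compared between the sets in the same way. The type I interferon, interferon gamma, MHC class II and megakaryocyte lists did not pass the test for a difference between VD and ZL (camera adjusted p of 0.761, 0.819, 0.133 and 0.819). This does not show that their genotype effects were equal. Their medians were -0.59, -0.54, -0.98 and -0.74 in VD and -0.95, -0.65, -0.64 and -0.64 in ZL, and the VD medians are the same with Oas2 and Cxcl10 at their floors. Nuclear oxidative phosphorylation genes had a median of -0.20 in VD and 0.39 in ZL (camera adjusted p for the difference 1.24e-14), and ribosomal protein genes of -0.04 and 0.51 (4.36e-12). MYC targets had medians of -0.22 and 0.06 (0.000184) and the JAK-STAT core of 0.01 and -0.34 (0.0311), where camera's direction in VD was lower although the median was above 0. With an estimated correlation none of these 4 differences passed (adjusted p = 0.843 for each).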

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

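Of the tests reported in this part, those on the Jak1 count, those on the ribosomal and oxidative phosphorylation lists taken separately, the count of splits with an estimated correlation and the splits within name sets were chosen after the result was seen.

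The first pattern is that Jak1 was not lower in the libraries labelled Jak1 KO while interferon genes were. Labels exchanged for some of the libraries are argued against by the type I interferon score, by which 0 of the 12 libraries lay nearer the other genotype of their name set, whereas an exchange of the whole groups would not show in it. All 57 tested type I interferon genes kept a median of 59.3% of their wt expression (quartiles 28.4% and 74.2%). This argues against libraries labelled Jak1 KO made up almost wholly of undeleted cells only if the deletion, and not cre, lowered these genes. The design cannot tell those apart, so the values do not decide it. A smaller share of undeleted cells stays open in either case. Reads from exons that the deletion leaves in place may account for a count that was not lower, but the gene-level log2 fold change of 0.18 cannot be told apart from other causes without counts per exon, which were not analysed here. Loss of Jak1 function, the biological difference the design names, stays open as a hypothesis and cannot be told apart from an effect of cre.

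The second pattern is the lower level of megakaryocyte and platelet genes. A trend with transcript length is argued against as the whole cause, because the list's median log2 fold change was -0.74 before and -0.74 after each library's length trend was removed (camera adjusted p = 4.40e-16). Platelet or megakaryocyte RNA carried over into the wt libraries predicts that platelet-restricted genes fall at least as far as the 4 genes of the list fixed as ones that stem cells also use. The 8 tested platelet-restricted genes (Ppbp at 10.7 CPM in wt, Gp9 at 51.5 and Gp5 at 64.9 among them) had a median of -0.43 against -0.99 for those 4. That median lay above the bound of -0.5 set beforehand by less than 0.121. This value is the SE of a weighted mean of the 8 genes taken as independent, and not the SE of the median. The difference between the scores of the 2 kinds of gene (0.34) did not pass an exact two-sided permutation test (p = 0.475 over 400 relabelings). Carry-over therefore cannot be told apart from a change within the stem cells, for which the genotype is a candidate cause. Whether the sort for LT-HSCs removed all platelets and megakaryocytes was not tested. The neutrophil gene S100a9 ranged from 149.9 to 415 CPM in VD libraries and from 2.21 to 4.38 in ZL libraries.

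The third pattern is that ribosomal protein genes (set-by-genotype adjusted p = 4.36e-12) and nuclear oxidative phosphorylation genes (1.24e-14) had different genotype effects in the name sets, with medians of -0.04 and -0.20 in VD and of 0.51 and 0.39 in ZL. Removal of the length trend took the median difference between the sets from 0.55 (quartiles 0.47 and 0.62) to 0.18 (0.093 and 0.38) and from 0.62 (0.52 and 0.73) to 0.26 (0.11 and 0.49), and both still passed (adjusted p = 0.00108 and 1.64e-06), but the 95% intervals of the score differences over the libraries held 0 before and after (after: -0.27 to 0.70 and -0.16 to 0.78), so that this trend cannot be told apart from other causes. Without the library labelled Jak1 KO 4 the ribosomal difference did not pass (0.143; median 0.085), which is consistent with that library as its source, while the oxidative phosphorylation difference passed (0.000813) with a median of 0.17 and a score interval of -0.47 to 0.86, which leaves that library open as a source too. With an estimated correlation neither passed (adjusted p = 0.843 for both), so members that vary together from library to library may account for both. The name sets also differed in sex (2 female libraries in VD and 4 in ZL), Rn45s share, depth and neutrophil transcripts. With the preset correlation both differences still passed with a term for sex (camera adjusted p = 2.12e-11 and 9.36e-14). They also passed with Rn45s and Lars2 left out (1.86e-12 and 6.15e-15). Those fits leave open a genotype effect that differs between the sexes. Depth and neutrophil transcripts were not tested as causes, and no biological explanation was tested.

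For the count of 58 genes as a whole, the splits argue against chance, but they do not clear each gene. Among 100 splits of the 12 libraries, the real one included, 1 gave as many, and the highest of the others gave 10. That split put all 6 female libraries on one side. These splits may be uneven over the name sets, and among 100 splits with 3 libraries of each set on each side, 1 gave as many and the highest of the others gave 0. For the 11 gene lists past camera's preset-correlation threshold chance cannot be excluded, since 12 of the 100 splits gave as many and the highest gave 16 (11 of 100 within name sets, highest 13). For the 4 lists past it with an estimated correlation, 3 of the 100 splits gave as many, the real one included, and the highest of the others gave 5. That share is under 0.05, but another split gave more than the real one, and the rule was written after the result was seen. The split with 5 lists and the other one with 4 each had 5 libraries of 1 genotype on one side, so both lie near the real grouping. With the rule written afterwards, the 100 splits are not taken to exclude chance for that count. Within name sets 1 of 100 gave as many and the highest of the others gave 2. For the 142 genes of the VD set alone, the real split was the 1 of 10 with as many and the highest of the others gave 1, and 10 splits are too few for a share under 0.05.

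MYC targets (set-by-genotype adjusted p = 0.000184) and the JAK-STAT core list (0.0311) also differed between the name sets with the preset correlation, and neither passed with an estimated one. In 20 of 200 groups of 6 (72 genes and 28 lists in each genotype) a library stood apart from the other 5 on set-adjusted log2 CPM by a gap whose share of the group's range was above Dixon's 95% critical value for 6 values. Chance gives about 1 in 20, or 10 of the 200, where the 6 values have equal spread. The biological coefficient of variation was 0.413 in ZL against 0.190 in VD, and the groups share libraries. The count of 20 therefore does not show an excess of outlying libraries. The library labelled Jak1 KO 4 was highest among those of its genotype for Cxcl10 (gap 0.721 of the range), Rtp4 (0.710), H2-Aa (0.700), H2-Ab1 (0.685), the MHC class II list (0.665) and Cd79b (0.724), and lowest for Jak2 (0.673). The library wt 6 was highest for Tyk2 (0.754), Stat3 (0.719), Stat5a (0.703), the JAK-STAT core list (0.692) and the cytokine receptor list (0.631), and lowest for Uqcrfs1 (0.669). Jak1 KO 4 and wt 6 had the lowest limma-voom quality weights, 0.165 and 0.215. Relative to their name set, their log2 CPM trended with exon length in opposite directions (Spearman -0.52 and 0.38). Whether these trends set their outlying values was not tested. The library wt 4 was highest for Jak2 (0.831) and Rb1 (0.782). Single libraries stood apart for Phf11d (Jak1 KO 1 lowest, 0.673), Igtp (wt 1 highest, 0.639), Lifr (wt 3 lowest, 0.717), Clca1 (Jak1 KO 3 highest, 0.761) and the T and NK cell list (wt 2 lowest, 0.772).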

How the results depend on the processing

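The length offset, the surrogate variable, the removal of Rn45s and Lars2 and the removal of 3 ZL libraries together were chosen after the data were seen. All 58 genes kept their direction in every alternative in which they were tested (55 of 58 under the 1 CPM filter, 3 not tested there), as did the interferon, MHC class II and megakaryocyte lists wherever lists were tested, which also stayed past the threshold there. Over single genes and alternatives, 1816 results kept direction and side, 116 lost the threshold, 36 gained it, 15 moved without a call and 0 reversed. Over the lists not past the threshold, 376 results stayed so with the same direction, 17 gained it, 94 moved and 6 reversed. The causes of the changes below were not tested unless fewer libraries entered. The count of genes was 126 with DESeq2 (28 higher, 98 lower, and 1 gene for the interaction), 220 with limma-voom (46 higher, 174 lower), 124 with 1 surrogate variable (11 higher, 113 lower) and 96 without the 3 ZL libraries (8 higher, 88 lower). It was 14 without the set term (0 higher, 14 lower), 142 in VD alone (46 higher, 96 lower) and 0 in ZL alone (0 higher, 0 lower). Genes higher numbered 3 without a low-count filter, 3 with the length offset, 3 at an adjusted p of 0.1, and 0 to 2 with 1 library left out. Replicate numbers were not taken to pair the samples, since the labels do not say so and wt and Jak1 KO deviations correlated at 0.0429 to 0.668, below 0.1 for 2 of 6 numbers. Sex was the same for 6 of 6 numbers, and whether animals were paired stays unknown. As a replicate block they gave 72 genes (2 higher, 52 shared with the 58), and 3 of 6 wt and 3 of 6 Jak1 KO libraries correlated best with their own number. With an estimated correlation 4 lists passed (adjusted p = 0.357 for the JAK-STAT core and S phase, 0.165 for G2/M, 0.772 for ribosomal proteins, 0.763 for MYC targets, 0.243 for lymphoid-primed progenitors and 0.266 for erythroid markers). With fry 5 passed (0.172 for the JAK-STAT core, 0.134 for S phase and lymphoid-primed progenitors, 0.731 for ribosomal proteins, 0.445 for MYC targets, 0.167 for erythroid markers). The ribosomal list turned lower with limma-voom (0.838) and in VD alone (0.376), and lost its call with 1 surrogate variable (0.526) and without the 3 ZL libraries (0.0934). With 1 library left out it ranged from 4.44e-11 to 0.968, the latter, without Jak1 KO 4, turned lower. The oxidative phosphorylation list turned lower with limma-voom (2.27e-06), in VD alone (2.41e-09), with 1 surrogate variable (3.65e-05), without the 3 ZL libraries (0.00927) and, over a range from 0.000113 to 0.925 with 1 library left out, without Jak1 KO 4 (0.000113). Cytokine receptors turned higher in VD alone (0.0430), and MYC targets turned higher in ZL alone (0.837) and lost their call without the set term (0.0599). Lymphoid-primed progenitor markers lost theirs without a low-count filter (0.223), with the 1 CPM filter (0.0961), the replicate block (0.0642), the sex term (0.0968) and in ZL alone (0.163). Erythroid markers lost theirs with limma-voom (0.0785) and in ZL alone (0.0504), as did S phase in ZL alone (0.120). With 1 library left out the adjusted p ranged from 0.000362 to 0.264 for MYC targets, from 0.00336 to 0.134 for lymphoid-primed progenitors and from 0.000784 to 0.239 for erythroid markers. The Jak1 log2 fold change ranged from -0.046 to 0.34 in those fits. At the real depths about 50% of simulated log2 changes of 1 were recovered, and what more depth would add was not tested.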

Other observations

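The genes of this part were chosen, and the name sets tested against each other, after the results were seen. Among the genes past the threshold that no list holds were Mfsd2b, a sphingosine-1-phosphate exporter of red cells and platelets (192 ± 33.4 CPM in wt and 79.4 ± 14.0 in the libraries labelled Jak1 KO, 2.43-fold lower), and Slc14a1, the urea transporter of red cells (308 ± 113 and 149 ± 37.2, 1.99-fold lower). Pde10a, a phosphodiesterase, was 3.66-fold lower (24.1 ± 5.87 and 6.74 ± 1.86), and Ache, acetylcholinesterase, 2.44-fold lower. Sdpr (now Cavin2), a caveolar coat protein, was 1.67-fold lower. These 5 genes stayed past the threshold in each of the 12 fits that left out 1 library. F2rl2, the protease-activated receptor 3 gene, was 2.28-fold lower and missed the threshold without wt 1, wt 4, wt 5, Jak1 KO 2, Jak1 KO 3 or Jak1 KO 5 (adjusted p up to 0.107).

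Between the name sets 7905 of the 13184 genes passed edgeR's threshold in the model with genotype, against 58 between the genotypes. Neutrophil and myeloid progenitor markers were far higher in VD. S100a9, a neutrophil alarmin subunit, ranged from 149.9 to 415 CPM in the 6 VD libraries and from 2.21 to 4.38 in the 6 ZL libraries, and Ltf, lactoferrin, from 79.3 to 223 and from 0 to 1.71. In that list 13 of 15 genes were lower in ZL and 0 higher (median log2 fold change -6.39, camera adjusted p = 4.81e-12, adjusted p = 0.644 with an estimated correlation), and the score gave an exact two-sided permutation p of 0.00216, the smallest that 6 against 6 can give (0.0121 adjusted over 28 lists). Nuclear oxidative phosphorylation genes were higher in ZL for 57 of 62 genes and lower for 0 (median 1.08, camera adjusted p = 1.83e-07, adjusted p = 0.921 with an estimated correlation, exact adjusted p = 0.0121). Mki67, a proliferation antigen, stood at 616 ± 82.8 CPM in VD and 137 ± 41.7 in ZL, while Ccnb1, a mitotic cyclin gene, went the other way (30.9 ± 8.52 and 75.3 ± 9.27), and the G2/M list as a whole did not pass (camera adjusted p = 0.268). The exact test passed for 10 of the 28 lists and camera with an estimated correlation for 0.

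Xist and Y-linked genes put replicates 1, 3 and 4 of each genotype among male animals and replicates 2, 5 and 6 among female ones, so the sexes were balanced between genotypes. In the 2 female VD libraries Xist was at 3386 CPM (wt 2) and 3846 CPM (Jak1 KO 2), and in the 4 female ZL libraries it ran from 359 to 581 CPM.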
